A study of Rattus norvegicus with 4 samples.

How the data were processed

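Gene expression was measured in the soleus, a slow postural muscle of the hindlimb, of female rats with Affymetrix GeneChip arrays, on which each transcript is read by 1 or more probe sets. The labels give 4 arrays in 2 groups of 2. Control rats moved freely in their cages, and unloaded rats were kept off their hindlimbs for 10 h of each day over 11 days. Each array was hybridised with RNA pooled from 4 to 5 rats, so a replicate is a pool, and spreads and p-values describe differences between pools and not between single animals.

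The authors deposited 1 table of intensity values per probe set and array, which per the submitters' processing notes were made with MAS5 (version not given in the sources used here). The deposited intensities are on a linear scale. Their trimmed mean, leaving out 2% of probe sets at each end, was 150.2 or 150.3 on all 4 arrays, as per-array scaling to a common target gives. The median signal was 35.6 and 34.6 on the control arrays and 34.9 and 33.9 on the unloaded arrays. Detection calls and array batches were not used here, and MAS5 settings beyond the name are not given in the sources used here. MAS5 signals of dim probe sets are noisy, and a common scale assumes that total mRNA signal was alike in the groups.

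The table holds 8799 probe sets, of which 59 Affymetrix control probe sets were left out. The remaining probe sets were named through the platform's annotation table, with symbols updated by gene ID to the RefSeq table of the rat assembly GRCr8. Of these, 7006 probe sets had 1 symbol (6985 matched the RefSeq table and 21 kept their older name), 308 had several and 1426 had none. No coordinates were used. Signals were transformed as log2(signal + 9), where 9 is the 25th percentile of all signals. Fold changes are on that scale, which understates the change of dim transcripts. Probe sets with a mean signal of at least 21.0, the 40th percentile, were tested, leaving 5257 probe sets and 3152 genes with a single-symbol probe set. No further normalization was applied.

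Unloaded and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), and p-values were adjusted by the Benjamini-Hochberg method over all tested probe sets, with 0.05 as the threshold. The fit had 2 residual and 5.80 prior degrees of freedom. Probe sets at least 1.5-fold apart in all 4 between-group array pairs were also counted, and the same count was made for both other divisions of the arrays into 2 and 2. Gene lists were tested with limma's camera (preset inter-gene correlation of 0.01, 1 probe set per gene, the one with the highest mean log2 signal), adjusted over 22 lists with at least 5 measured genes. Listed symbols that had since been renamed were updated through RefSeq synonyms. The lists covered contractile isoforms, energy metabolism, protein turnover, matrix, stress responses, growth control, the neuromuscular junction, immediate early genes, the clock, and markers of adipocytes, endothelium, smooth muscle, blood, leukocytes and Schwann cells. There were 2 genes in more than 1 list.

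The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took up to 12 genes per direction with the largest change among single-symbol probe sets that passed and whose groups did not overlap, a fixed set of muscle genes whatever their values, and up to 4 members of each list with the smallest p. For the first part of the rule the probe set with the smallest p stands for a gene, and for the others the probe set with the highest mean log2 signal. Of the fixed genes, Ppargc1a, Fbxo32, Mstn, Mt1 and Mt2A had no tested probe set with 1 symbol.

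The steps were tested on simulated data for the 5257 probe sets of this comparison, with 200 probe sets changed in each of 20 runs. The fit recovered 31.2% of 1.5-fold, 78.5% of 2-fold and 99.7% of 4-fold changes, with a mean of 5.66% false calls. Simulated errors were independent and normal, with variances drawn from the prior of the fit. These shares therefore hold under the fit's own assumptions and can differ in the real arrays. With no simulated change the mean was 0.05 calls. A list of independent genes shifted by 0.3 on the log2 scale was called in 20 of 20 runs.

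Alternatives were quantile normalization, median scaling, other offsets and filters, no mean-variance trend, the pool number as a block, leaving out each array, other thresholds, genes in place of probe sets, and for the lists an estimated correlation, limma's fry, the mean over a gene's probe sets and 10000 random lists matched on signal. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.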

Results

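Soleus RNA from caged control rats (2 pools) was compared with soleus RNA from rats whose hindlimbs were unloaded for 10 h a day over 11 days (2 pools), to ask which transcripts of a postural muscle differ after repeated daily inactivity. Each pool held RNA of 4 to 5 rats and was read on 1 array. Over the 5257 tested probe sets, log2 signals correlated at 0.987 between the control pools and 0.988 between the unloaded pools, against 0.973 to 0.974 between pools of different groups. The median SD between pools of a group was 0.11 log2 in controls and 0.10 in unloaded rats. Values below are mean signals ± SD with n = 2 pools per group, log2 fold changes are unloaded minus control with their standard error (SE), and adjusted p-values are from limma with Benjamini-Hochberg adjustment. The number of arrays limits the precision.

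In the unloaded soleus the lists of immediate early and heat shock transcripts shifted down, and those of fast-fibre contraction, glycolysis and the TCA cycle shifted up. None of these 5 calls held with an estimated correlation between genes (adjusted p = 0.440 to 0.586). That test rests on the 2 residual degrees of freedom of the fit. Its power over 22 lists was not measured, so a call lost there does not show that a list was unshifted. For fast-fibre and TCA cycle genes the estimated correlation (0.147 and 0.069) lay above the preset 0.01, so their preset p may be too small. By fry the 2 downward calls held, and the upward ones did not (adjusted p = 0.0785 to 0.199). The orphan nuclear receptor Nr4a1 fell from 852.6 ± 29.5 to 126 ± 8.98 signal units, 6.37-fold lower (log2 fold change -2.67, SE 0.11, adjusted p = 4.7e-05). The lipolysis inhibitor G0s2 rose from 23.8 ± 4.95 to 300.5 ± 21.6, 9.48-fold higher (log2 fold change 3.24, SE 0.15, adjusted p = 5.5e-05). Myh7, the slow myosin heavy chain, did not pass (-0.13, SE 0.09, adjusted p = 0.485). Its probe set was the brightest on both control arrays, and whether so high a signal can still register a fall was not tested.

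In all, 136 probe sets were higher and 140 lower in the unloaded pools at an adjusted p under 0.05, out of 1092 at an unadjusted p under 0.05. They covered 95 genes that rose and 84 that fell, with 17 called probe sets annotated to several genes and 29 to none. Changes of at least 2-fold were seen in 32 of the higher and 50 of the lower probe sets. Both unloaded pools lay at least 1.5-fold above or below both control pools for 157 probe sets (69 higher, 88 lower), against 3 and 17 for the other divisions of the 4 arrays into pairs. There limma called 0 probe sets in each, with 60 and 97 at an unadjusted p under 0.05. Those divisions put a control and an unloaded pool together, so the difference between the groups widens their spread and lowers such counts. The 3 divisions are too few for a share under 0.05. With 1 array left out, fewer probe sets passed, 43 higher and 41 lower without control pool 1, 29 and 38 without control pool 2, 22 and 55 without unloaded pool 1, and 26 and 46 without unloaded pool 2. The counts were 42 and 48 without a filter on dim probe sets, and 52 and 61 without a mean-variance trend.

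**Figure D1:**
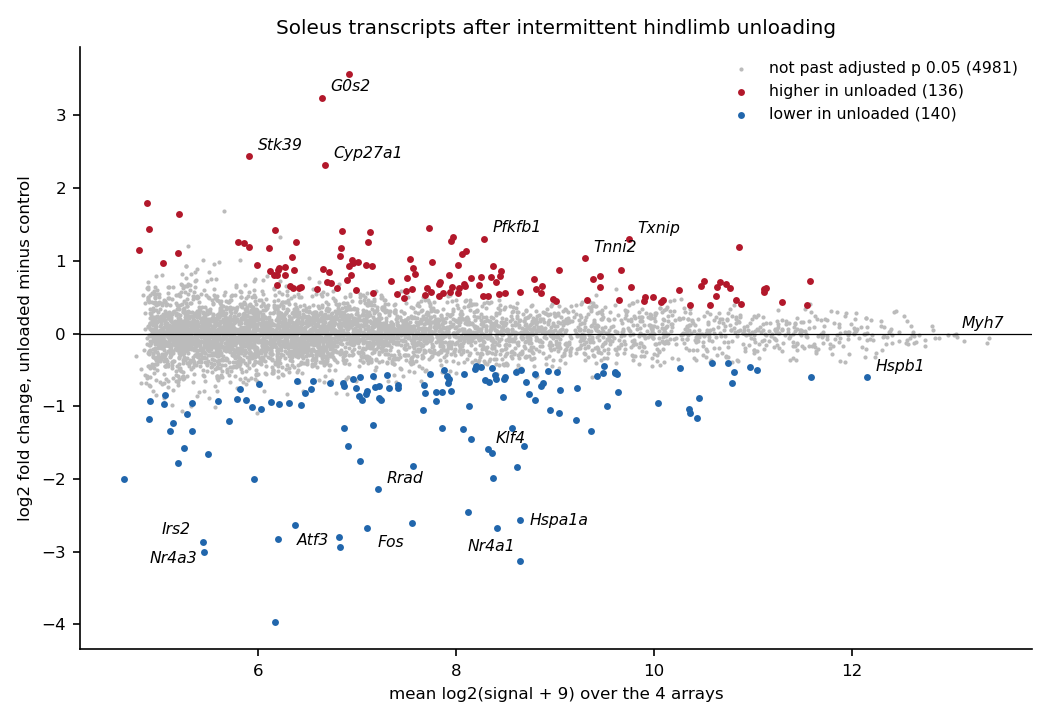
Log2 fold change (unloaded minus control) of each tested probe set against its mean log2(signal + 9) over the 4 arrays, with 1 point per probe set. The 136 higher (red) and 140 lower (blue) probe sets are those with a limma adjusted p under 0.05, and G0s2 at 3.24 and Nr4a3 at -3.01 are among the labelled genes.

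Among the most strongly reduced named transcripts were regulators that cells induce quickly and briefly. Nr4a3 fell by 3.01 on the log2 scale (SE 0.22), from 117 ± 34.4 to 6.40 ± 0.849. Irs2, an adaptor of the insulin receptor, fell by 2.87 (SE 0.19), from 109 ± 14.0 to 7.15 ± 1.77 (-1.66, SE 0.30, and -0.99, SE 0.19, on its 2 other probe sets), and the stress-induced factor Atf3 fell by 2.79 (SE 0.16), from 289.9 ± 57.9 to 33.8 ± 3.04. The remaining genes with the largest declines were Fos (-2.68), Hspa1a (-2.57), the small GTPase Rrad (-2.14), Ppp1r15a (-1.99), Id1 (-1.82) and Nr4a2 (-1.78), together with the matricellular gene Ccn1 (4.01-fold lower) and the neurotrophin Bdnf (3.99-fold lower), with adjusted p from 5.5e-05 to 0.0126. Unloaded signals of Nr4a3, Irs2 and Bdnf (3.85 ± 4.31) lay under the offset of 9, so their folds carry the offset. With the offset at the 50th percentile Nr4a3 gave -1.87, Irs2 -1.77, Bdnf -0.98 and Nr4a2 -1.03. Other probe sets gave smaller falls of Fos (-1.84, SE 0.14) and Nr4a2 (-0.96, SE 0.21). A dimmer probe set of Id1 gave -0.27 (SE 0.19) and the brightest of Bdnf -0.77 (SE 0.53), and neither passed.

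Among rising transcripts, Stk39, a kinase that acts on ion cotransporters, went from 17.2 ± 6.86 to 132 ± 13.1 (log2 fold change 2.44, SE 0.21, adjusted p = 5.5e-04). Its 2 other probe sets gave 0.37 (SE 0.21) and -0.61 (SE 0.29) and did not pass. In controls these were brighter than the called one, at 36.75 ± 11.7 and 27.75 ± 8.27. Cyp27a1, the mitochondrial sterol 27-hydroxylase, rose from 36.7 ± 0.283 to 220.2 ± 23.8 (2.32, SE 0.14, adjusted p = 1.4e-04), and by 0.91 (SE 0.11) on another probe set. Further rises were seen in Mchr1 (1.79), the lysosomal lipase Lipa (1.44), Grhpr (1.43), Klf10 (1.41), Cited2 (1.39), the cytokine Il15 (1.32), Pfkfb1 (1.30), the glucose-uptake inhibitor Txnip (1.29) and Ucp3, an uncoupling protein of muscle mitochondria (1.27), with adjusted p from 2.8e-04 to 0.0262. The unloaded pools of Grhpr differed most, at 115 ± 51.8 against 35.0 ± 6.15 in controls, and its 2 other probe sets gave 0.19 (SE 0.18) and -0.07 (SE 0.22) and did not pass. The rises of Mchr1 and Lipa rest on dim probe sets, with control signals of 6.75 ± 1.06 and 9.20 ± 2.97, while their brightest probe sets gave 0.28 (SE 0.14) and 0.26 (SE 0.11) and did not pass. With the offset at the 50th percentile the rises were 0.96 and 0.77. Cited2 rose by 0.64 on its 2 other probe sets and Il15 by 1.26 and 0.87. The 3 dimmer probe sets of Pfkfb1 gave -0.25 to 0.50 and did not pass either.

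**Figure D2:**
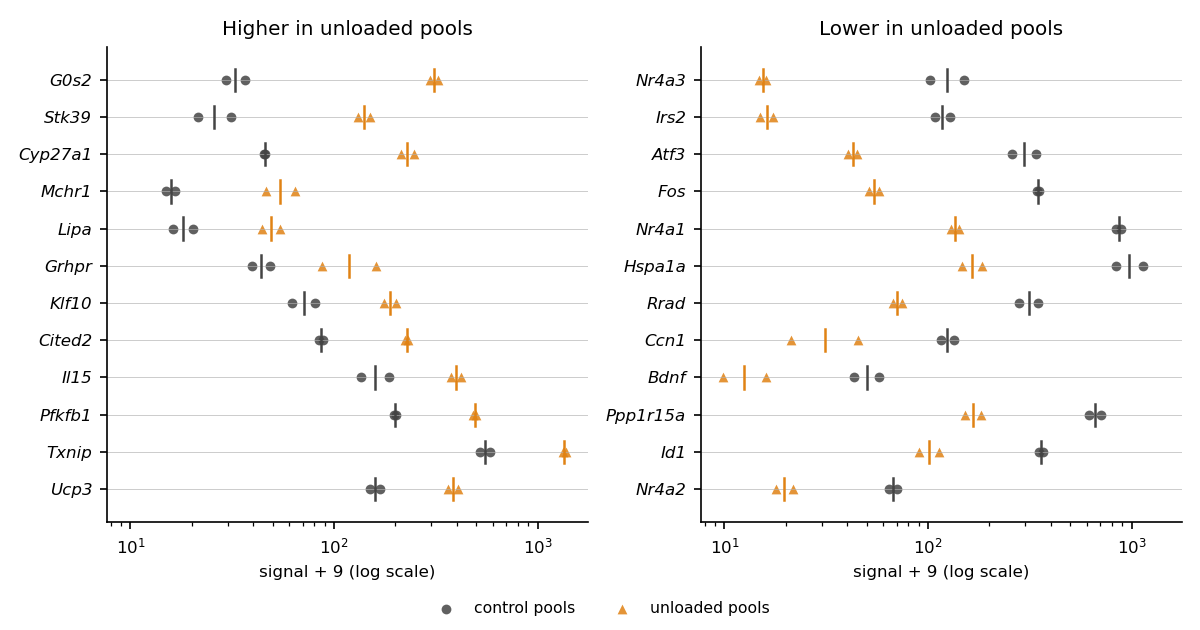
Signal plus 9 (log scale) in each control pool (grey circles) and unloaded pool (orange triangles) for the 12 genes with the largest rise and the 12 with the largest fall among those that passed, with bars at the mean of log values. In each gene both unloaded pools lie on one side of both control pools, as for Txnip (542 ± 42.8 in controls, 1342 ± 38.8 in unloaded rats).

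Of 57 named probe sets that passed, 19 also passed whichever array was left out and in each of the 12 alternatives run on single genes. They stand for G0s2, Stk39, Cyp27a1, Cited2, Pfkfb1, Txnip, Ucp3, Nr4a3, Irs2, Atf3, Fos, Nr4a1, Hspa1a, Rrad, Ppp1r15a, Id1, Fgf1 and Klf4. Of the 56 genes with a named probe set that passed, 14 had another tested probe set that did not. Without control pool 1, 33 of the 57 passed, without control pool 2, 24, without unloaded pool 1, 28, and without unloaded pool 2, 23.

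The immediate early and activity-responsive list shifted down. In this and the other lists a gene is counted by its brightest probe set. Of 25 measured genes, 11 fell, 1 rose and 13 did not pass, and adjusted over the list alone 13 fell and 4 rose. Its median log2 fold change was -0.58 (camera adjusted p = 1.8e-06), with adjusted p = 0.440 with an estimated correlation, and without a filter on dim probe sets the median was -0.28. Besides Nr4a1, Atf3 and Fos, the zinc-finger factor Klf4 fell by 1.59 (SE 0.10), the phosphatase Dusp1 by 1.00 (SE 0.10) and Ier3 by 1.30 (SE 0.16). Klf10 was the member that rose. Egr1 (-0.66, SE 0.24), Junb (-0.79, SE 0.23) and Jun (-0.13, SE 0.09) did not pass, with adjusted p of 0.174, 0.0987 and 0.475.

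Heat shock transcripts also shifted down. Of 25 heat shock and chaperone genes, 5 fell and 20 did not pass, against 9 lower and 3 higher adjusted over the list alone. The median was -0.22 (camera adjusted p = 5.7e-05), with adjusted p = 0.440 with an estimated correlation. The inducible chaperone Hspa1a dropped from 976 ± 211 to 156 ± 26.5, and 4 probe sets annotated to both Hspa1a and its near-identical copy Hspa1b fell by 2.45 to 3.96, so the copies are not told apart. The cochaperones Dnajb5 (-1.06, SE 0.13), Dnajb1 (-0.75, SE 0.12) and Dnaja1 (-0.68, SE 0.13) fell, as did the small heat shock protein Hspb1 (-0.60, SE 0.09). Second probe sets of Dnajb1 (-0.41, SE 0.15) and Dnaja1 (-0.50, SE 0.14) and 2 of 4 of Hspb1 (-0.38 and -0.32) did not pass. Hsp90ab1 fell on a dimmer probe set (-0.46, SE 0.10) but did not pass on its brightest (-0.32, SE 0.09). Probe sets annotated to both Hsp90aa1 and Hsp90aa1-ps17 gave -1.34 (SE 0.09, adjusted p = 2.4e-04) and -1.30 (SE 0.13, adjusted p = 0.00107). Cryab, another small heat shock protein, gave -0.14 (SE 0.10, adjusted p = 0.513). In the antioxidant and metal stress list, Nqo1 (-0.93, SE 0.14) and Hmox1 (-0.81, SE 0.16) fell and 30 of 32 genes did not pass, with a list median of -0.08 (camera adjusted p = 0.0525). The list passed in 5 of 16 alternatives, among them the one without unloaded pool 2 (adjusted p = 0.0347), over a range of 0.0207 to 0.472. The list median ranged from -0.13 to -0.05 over these alternatives. Adjusted over the list alone, 5 fell and 1 rose. A dimmer probe set of Gsta1 also fell (-0.45, SE 0.10).

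Fast-fibre transcripts rose as a list, and slow-fibre transcripts did not pass as one. In the fast list 7 of 13 genes rose and 6 did not pass, also 7 adjusted over the list alone, with a median of 0.46 (camera adjusted p = 5.7e-05), and adjusted p = 0.472 with an estimated correlation and 0.131 by fry. Tnni2, fast troponin I, rose from 436 ± 87.2 to 898 ± 16.3 (1.04, SE 0.14, adjusted p = 0.00549). The fast calcium pump Atp2a1 (0.73, SE 0.10), the light chain Myl11 (0.71, SE 0.10), Tnnt3 (0.68, SE 0.11) and Myh2, the heavy chain of type 2A fibres (0.63, SE 0.14), rose too, with Myh2 at 0.42 and not past the threshold without control pool 2. Myh1 (-0.04, SE 0.21), Myh4 (0.15, SE 0.21) and Pvalb (-0.14, SE 0.19), typical of the fastest fibres, did not pass. Of 10 slow-fibre genes 1 passed, also adjusted over the list alone, the light chain Myl6b (-0.70, SE 0.15, adjusted p = 0.0426), and the list median was -0.01 (camera adjusted p = 0.833). Tnni1 (-0.01, SE 0.09), Csrp3 (0.22, SE 0.12) and the slow calcium pump Atp2a2 (0.17, SE 0.09) did not pass.

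Glycolytic transcripts moved up as a list. Of 20 genes 5 rose and 15 did not pass, against 9 higher and 3 lower adjusted over the list alone. The median was 0.25 (camera adjusted p = 0.00869), with adjusted p = 0.472 with an estimated correlation and 0.0785 by fry. Pfkfb1, which sets the level of a phosphofructokinase activator, went from 189.9 ± 2.69 to 482 ± 12.4 (adjusted p = 3.1e-04). Gpd1 (1.26, SE 0.16), the muscle phosphofructokinase Pfkm (0.57, SE 0.09) and the pyruvate kinase Pkm (0.52, SE 0.09) rose, with a dimmer Pfkm probe set at 0.08 (SE 0.09). The phosphoglycerate mutase Pgam1 gave -0.36 (SE 0.11, adjusted p = 0.123) on its brightest probe set and -0.60 (SE 0.14) on its dimmest, and fell on the one between (-0.83, SE 0.10, adjusted p = 0.00476). Hexokinase Hk2 gave -0.59 (SE 0.14, adjusted p = 0.0514) on one probe set and -0.05 (SE 0.11) on another, and the glucose transporter Slc2a4 gave 0.06 (SE 0.09). None of 15 genes of the TCA cycle and pyruvate dehydrogenase passed on its brightest probe set, with 3 higher adjusted over the list alone. Their median was 0.22 (camera adjusted p = 0.0294), with adjusted p = 0.586 with an estimated correlation. That call was lost without control pool 2 (median 0.13, adjusted p = 0.207) and without unloaded pool 1 (adjusted p = 0.0856), with quantile normalization (0.0744) and without a mean-variance trend (0.104), within a range of 0.00753 to 0.586 over its alternatives. With the mean of a gene's probe sets the median was 0.12. Pdhb gave 0.45 (SE 0.11, adjusted p = 0.0641) on its brightest probe set and rose on a dimmer one (0.71, SE 0.14, adjusted p = 0.0318). Cs gave 0.41 (SE 0.11), Got1 0.41 (SE 0.11) and Dlat 0.27 (SE 0.10).

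Among 31 genes of fatty acid uptake and oxidation 4 rose, none fell and 27 did not pass, against 5 higher and 3 lower adjusted over the list alone. Ucp3 rose from 149.9 ± 12.4 to 375 ± 30.2, Acsl6 by 0.98 (SE 0.14), Cpt1a, the entry enzyme of mitochondrial fatty acid import, by 0.62 (SE 0.14), and Pdk4, which restrains pyruvate dehydrogenase, by 0.65 (SE 0.15, adjusted p = 0.0486). Cpt1a and Pdk4 each passed in 4 of 12 alternatives, and Pdk4 gave 0.43 without control pool 2 (adjusted p = 0.195). The list median was -0.02 and its mean 0.05 (camera adjusted p = 0.948). Lpl, the lipase that frees fatty acids from circulating triglyceride, gave -0.36 (SE 0.09, adjusted p = 0.0673) on its brightest probe set, -0.16 on another and -0.50 (SE 0.09) on a probe set that passed. Cd36 (-0.27, SE 0.10), Cpt1b (0.17, SE 0.09), Fabp3 (-0.05, SE 0.08) and Ucp2 (0.00, SE 0.12) did not pass. Oxidative phosphorylation had a median of -0.03 over 54 genes (camera adjusted p = 0.351; -0.10 and 0.0134 without control pool 1, within a range of 0.0134 to 0.953), where Atp5if1, the inhibitor of ATP synthase, fell (-0.53, SE 0.10; its 3 dimmer probe sets did not pass) and Ndufb2 (-0.38, SE 0.12), Ndufa8 (-0.37, SE 0.13) and Ndufb11 (0.29, SE 0.09) did not pass. Uqcrfs1 gave -0.01 (SE 0.10) on its brightest probe set and rose on a dimmer one (0.44, SE 0.09). Adjusted over the list alone, 1 gene was lower.

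**Figure D3:**
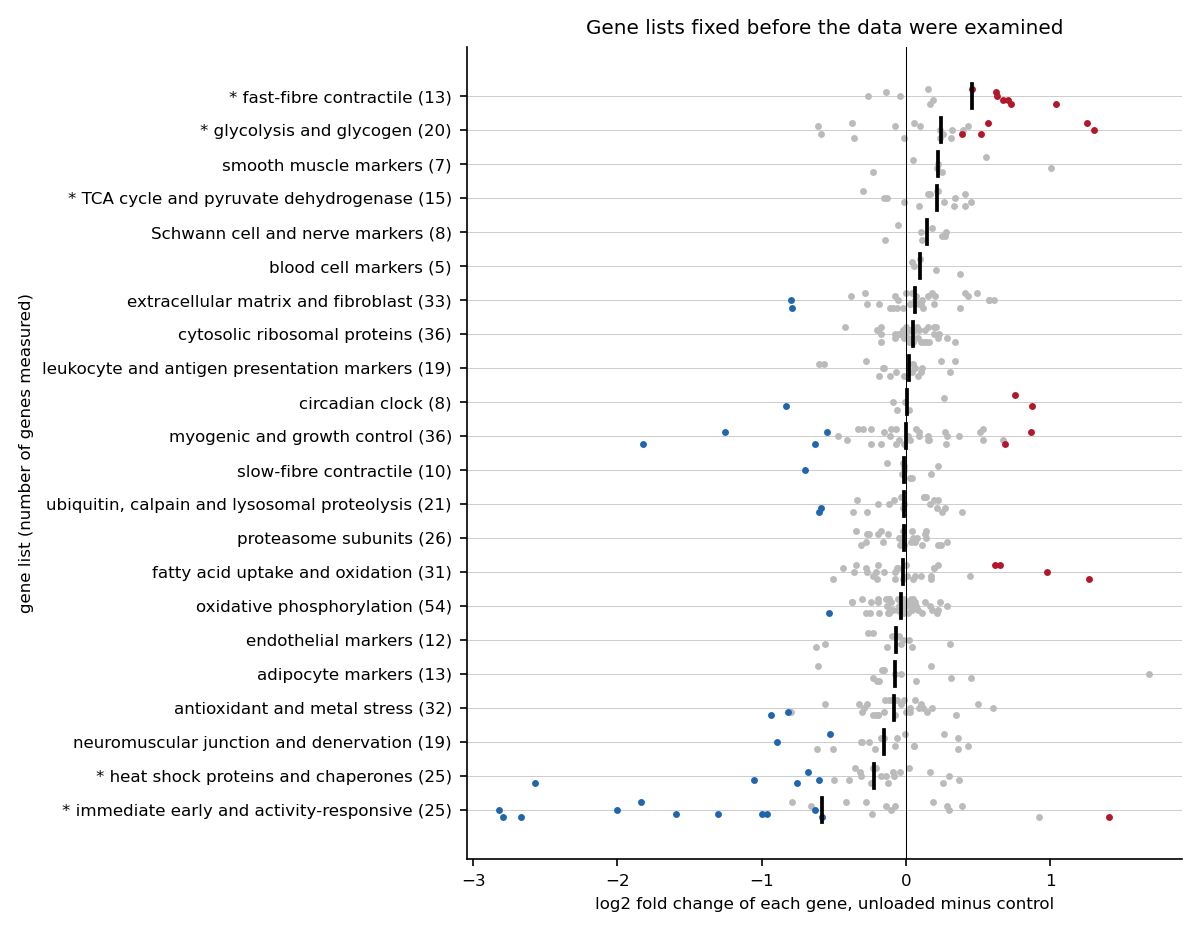
Log2 fold change (unloaded minus control) of each measured gene in the 22 lists, with the number of genes in brackets, black bars at list medians, and red or blue points for genes that passed an adjusted p of 0.05. Asterisks mark the 5 lists with a camera adjusted p under 0.05 at the preset correlation, from immediate early genes at -0.58 to fast-fibre genes at 0.46, and none of them passed with an estimated correlation.

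Transcripts of protein turnover gave small list shifts. Proteasome subunits had a median of -0.02 over 26 genes, none of which passed (camera adjusted p = 0.797), with Psmb4 at -0.34 (SE 0.10), Psma2 at 0.28 (SE 0.10), Psmb3 at -0.26 (SE 0.09) and Psma5 at -0.27 (SE 0.09). In the ubiquitin, calpain and lysosomal list 2 of 21 genes fell, also adjusted over the list alone where 1 rose (median -0.02, camera adjusted p = 0.833). They were Trim63, a muscle ubiquitin ligase, from 840.1 ± 100.3 to 554 ± 35.9 (adjusted p = 0.0262), and the calpain inhibitor Cast (-0.60, SE 0.13), whose 4 dimmer probe sets did not pass. Ctsl (0.39, SE 0.09) and Ube2b (-0.34, SE 0.11) did not pass. Cytosolic ribosomal proteins had a median of 0.05 over 36 genes, none past the threshold (camera adjusted p = 0.351), as for Rpl26 at 0.34 (SE 0.10).

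In the myogenic and growth control list, 2 of 36 genes rose, 4 fell and 30 did not pass, with 4 in each direction adjusted over the list alone (median 0.00, camera adjusted p = 0.833). Gadd45a (0.87, SE 0.11) and the myogenic factor Myog (0.68, SE 0.11) rose. Id1, Fgf1 (-1.25, SE 0.12), the angiogenic factor Vegfa (-0.63, SE 0.10) and the myogenic factor Myf6 (-0.55, SE 0.10) fell. Igf1 (0.09, SE 0.16), Myod1 (-0.07, SE 0.19) and Cdkn1a (-0.15, SE 0.40) did not pass. Of 19 neuromuscular junction and denervation genes, Chrnd, a subunit of the acetylcholine receptor, fell by 0.89 (SE 0.14) and Myh3, annotated as embryonic myosin, by 0.52 (SE 0.09), with a control signal of 2149 ± 34.9. Other Myh3 probe sets gave -0.74 (SE 0.11), -0.92 (SE 0.13) and -0.96 (SE 0.19), which passed, and -0.31 (SE 0.13), which did not. Whether any of them reads Myh3 apart from other myosins was not tested. Dmd (-0.62, SE 0.16) and Chrnb1 (0.43, SE 0.13) did not pass. Adjusted over the list alone 4 fell and 1 rose (median -0.15, camera adjusted p = 0.225), and the median was -0.05 without unloaded pool 2, -0.08 without control pool 2, -0.10 without control pool 1 and -0.07 without a filter or with the mean of a gene's probe sets.

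In the extracellular matrix list 2 of 33 genes fell, P4ha1 (-0.80, SE 0.12) and Serpinh1 (-0.79, SE 0.18), which modify and fold collagen, while Col1a1 (-0.08, SE 0.13), Col3a1 (-0.02, SE 0.10), Lox (0.57, SE 0.15), Dcn (0.41, SE 0.11) and Sparc (-0.27, SE 0.09) did not pass. On dimmer probe sets Dcn (0.87, SE 0.11, adjusted p = 0.0054), Lox (0.81, SE 0.18, adjusted p = 0.0469) and Sparc (0.60, SE 0.11, adjusted p = 0.0183) rose. Adjusted over the list alone the same number fell and 1 rose (median 0.06, camera adjusted p = 0.707). Without unloaded pool 2 the median was 0.15 and the adjusted p 0.0334, within a range of 0.0334 to 0.953. Of 8 clock genes, Per2 fell (-0.83, SE 0.13) and Nr1d1 (0.76, SE 0.12) and Bhlhe41 (0.87, SE 0.19) rose, also adjusted over the list alone, with Hlf at 0.27 (SE 0.21) and a median of 0.01 (camera adjusted p = 0.778).

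Markers of other cell types did not pass as lists, nor as single genes on the brightest probe set, while 1 of 3 probe sets of the smooth muscle marker Acta2 rose (0.82, SE 0.15, adjusted p = 0.0221; 0.25, SE 0.11 on the brightest). Medians were -0.08 for 13 adipocyte genes (mean 0.08, camera adjusted p = 0.992), -0.07 for 12 endothelial genes (0.383), 0.22 for 7 smooth muscle genes (0.290), 0.10 for 5 blood cell genes (0.329), 0.02 for 19 leukocyte genes (mean -0.04, 0.833) and 0.15 for 8 Schwann cell and nerve genes (0.707; median 0.09 without control pool 2 or unloaded pool 2 or with the offset at the 50th percentile). Over their alternatives the medians ranged from -0.10 to 0.02 for adipocyte, -0.20 to 0.02 for endothelial and -0.13 to 0.06 for leukocyte genes. Adjusted over the list alone, 2 adipocyte genes were higher. The adipocyte gene Scd gave 1.69 (SE 0.41, adjusted p = 0.0561), at 19.4 ± 6.65 in controls and 92.0 ± 64.1 in unloaded rats. Endothelial Kdr gave -0.63 (SE 0.31), smooth muscle Myh11 0.56 (SE 0.21), Hbb 0.21 (SE 0.08), the antigen-presenting RT1-Da 0.34 (SE 0.10) and Pmp22 -0.14 (SE 0.10).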

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

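The median log2 fold change of all probe sets moved by at most 0.01 under either other scaling. Quantile normalization called 118 higher and 124 lower, of which 114 and 118 were also called in the stated fit. The counts changed to 42 higher and 48 lower without a filter (8740 probe sets tested), and 52 and 61 without a trend. For neither was the cause tested. They were 72 and 65 over genes (fewer units), 226 and 232 at a threshold of 0.10, and 445 and 466 at 0.20. Leaving out each array (1 residual degree of freedom, the lone array taken to vary like the other group) gave 22 to 43 higher and 38 to 55 lower. The 1.5-fold count was 103 with the offset at the 50th percentile, which shrinks dim changes, and 282 to 303 with 1 array left out, where fewer pairs must differ. Pool numbers did not pair the arrays (correlation of deviations -0.04), and with them as a replicate block 78 were higher and 87 lower.

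Against 5 called lists, camera with an estimated correlation called 0 (2 at an unadjusted p under 0.05), fry 2 by direction (immediate early and heat shock) and 12 in either direction. With an estimated correlation camera tests on the 2 residual degrees of freedom. The estimate was -0.018 for immediate early, 0.0038 for heat shock and -0.029 for glycolytic genes, under the preset 0.01. A higher correlation thus does not explain the loss of those calls. It was 0.147 for fast-fibre and 0.069 for TCA cycle genes. Why fry differed was not tested. Other settings called 4 to 7. Of 57 named probe sets that passed, none changed sign in 12 alternatives. Of 67 that did not pass, 12 changed sign and 13 passed in some alternative. Without detection calls, signal over background was not judged.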

Other observations

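The genes in the next paragraphs, and the tests of RNA integrity, time of day, cell types, fast muscle and scaling, were chosen after the values were seen, and so were the bounds of those tests. The tests on other hypoxia-responsive, PPAR-responsive and branched-chain amino acid genes used genes whose values had not been seen. The branched-chain list was added after the hypoxia and PPAR results were known, and the adjustment over the 3 lists was chosen after all 3 results, in place of the unadjusted camera p stated beforehand. With either p no list is past 0.05.

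Several signalling and transport transcripts outside the fixed lists passed, each given by its probe set with the smallest p. Of 27 genes added after the values were seen (Pgam1 of the glycolysis list among them), 9 had another tested probe set that did not pass. Irs1 fell alongside Irs2, from 72.0 ± 10.1 to 34.0 ± 5.44 (SD, n = 2 pools), a log2 fold change of -0.92 (SE 0.18, limma Benjamini-Hochberg adjusted p = 0.0271), and Gipr, the receptor of an insulin-releasing gut hormone, fell by 0.91 (SE 0.19). Among single phosphodiesterase genes, Pde4a (0.94, SE 0.12), Pde4b (0.62, SE 0.11) and Pde2a (0.90, SE 0.17) rose and Pde7a fell (-1.11, SE 0.20), and the family was not tested. The sodium pump subunits Atp1b1 (0.75, SE 0.10) and Atp1b2 (0.97, SE 0.19) rose, the latter on the dimmest of 3 probe sets (-0.04 and 0.00 on the others). The 2 other probe sets of Pde4b gave 0.29 and -0.03. The Notch target Hes1 (1.10, SE 0.11) and the co-repressor Tle1 (1.26, SE 0.16) rose, whereas Smad7 (-1.57, SE 0.19) and Socs3 (-1.01, SE 0.20), which damp TGF-beta and cytokine signals, fell. Only 1 of the 27 genes passed in every alternative, Hes1, and none changed sign. With the offset at the 50th percentile the changes of the dim Smad7 (-0.93), Pde7a (-0.67), Atp1b2 (0.54), Pdp2 (-0.61) and Scarb1 (0.65) were smaller.

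Single genes of metabolism passed as well. Glutamine synthetase Glul fell by 0.78 (SE 0.10) and the AMP deaminase Ampd3 by 0.71 (SE 0.12). The phosphatases that activate pyruvate dehydrogenase went opposite ways, Pdp1 up (0.95, SE 0.12) and Pdp2 down (-0.93, SE 0.18), each on 1 of 2 probe sets. Alas1, the first enzyme of heme synthesis (0.78, SE 0.12), the transferrin receptor Tfrc (1.01, SE 0.14) and the lactate carrier Slc16a3 (1.05, SE 0.16) rose, as did the lipoprotein receptor Scarb1 (1.10, SE 0.21) on 1 of 3 probe sets. Cardiac actin Actc1 (-1.03, SE 0.21) and Fhl2 (-0.92, SE 0.13) fell. A probe set annotated to the myosin heavy chains Myh2, Myh1 and Myh8 gave the largest rise, 3.56 (SE 0.57), but its unloaded pools read 188 and 872.5, a log2 difference of 2.16, whereas the 7 fast-fibre genes that passed differed between those pools by -0.09 to 0.18. The control pools agreed less. Control pool 1 read above control pool 2 for Tnni2 (498 and 375), Myh2 (2078 and 1553), Atp2a1 (2549 and 2191), Myl11 (1351 and 1180) and Tnnt3 (1459 and 1226). Of 91 genes with several tested probe sets, at least 1 of them called, 15 had probe sets of opposite sign and none was called both ways.

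The fall of immediate early and heat shock transcripts is a pattern with technical candidates. RNA integrity could set it, but the log2 ratio of 3' to 5' control probe sets differed between groups by -0.061 for Actb and -0.021 for Gapdh, under the bound of 0.2 set for it. Fewer cells of another type would lower their markers by about as much as the genes that those cells express. The 16 genes that passed and fell had a median of -1.18. The lowest median of the 6 marker lists was -0.078, and each lay higher by more than the SD of its members. Those 16 genes were picked for having fallen. The whole immediate early and heat shock lists had medians of -0.58 and -0.22, less than the adipocyte SD (0.55) below the adipocyte median. A smaller loss of other cells is thus not excluded, and cell types without a list were not tested. The time of day of sampling cannot be told apart from the treatment, since 3 of 8 clock genes passed and sampling times are not in the labels. Among the clock genes that did not pass, Dbp gave -0.09 (SE 0.12), Tef -0.01 (SE 0.14), Nr1d2 0.02 (SE 0.10) and Bhlhe40 -0.06 (SE 0.12). Unloading itself, including whether rats had just stood or walked, stays open and was not tested.

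For the rise of fast-fibre and glycolytic transcripts, array scaling is a candidate. The median over 33 genes was 0.26 or more under 2 other scalings, but the arrays were already scaled alike and these moved the median of all probe sets by at most 0.0082, so this does not test it. The median of all tested probe sets was 0.0013, but scaling each array to a common target sets it near this level. It therefore cannot show whether total mRNA differed between the groups. Both lists lay at the 100th percentile of 10000 random lists matched on signal. A factor common to an array moves genes of like signal alike. The percentile thus argues against such a factor as the cause of the rise relative to other genes. Whether the lists rose in absolute amount stays open. Adjacent fast muscle in the dissected tissue may contribute. Myh4, Myh1 and Pvalb had a median of -0.041, against 0.68 for the 7 fast-fibre genes that passed, but their probe sets lay under the median signal (at most 6.28 against 6.68 log2) and the probe set shared by Myh2, Myh1 and Myh8 rose, so the test cannot exclude it. A change of fibre programme with unloading stays open, as untested.

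Further hypotheses concerned pathways around single genes. Vegfa, Hmox1, P4ha1 and the oxygen sensor Egln3 (-0.71, SE 0.12) fell, so a wider fall of hypoxia-responsive genes was tested. These genes were picked for having fallen. The test left out genes already named above, so hypoxia-responsive genes among those, including any that rose, were not weighed. Over 13 others the median was 0.00 (limma camera adjusted p = 0.707 over the 3 lists tested this way), with none past the threshold, so a wider fall was not detected. Ucp3, Pdk4 and Cpt1a rose (the last 2 in 4 of 12 alternatives each), but 15 other PPAR-responsive genes had a median of -0.13 and a mean of 0.00 (limma camera adjusted p = 0.707), again with none past it. Acadsb (-0.97, SE 0.17), Aldh6a1 (-0.72, SE 0.13) and Ivd (-0.54, SE 0.09, on 1 of 3 probe sets) of branched-chain amino acid catabolism fell with a median of -0.72. The 12 other genes of that pathway had a median of -0.16 (SD 0.23, limma camera adjusted p = 0.169), so as a set they did not fall by as much. But the 3 genes were picked because they passed, each by its probe set with the smallest p (Ivd gave -0.31 on its brightest). A weaker change in the other genes was therefore likely, and a smaller fall across the pathway stays open.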
